A study of Mus musculus with 8 samples.

How the data were processed

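Total RNA from mouse limb bud cells had been labelled and hybridised to 8 Illumina bead arrays (2 untreated, 3 AdLacZ, 3 AdCre) with 25697 probes, and per the labels BeadStudio 2.1 was among the authors' processing tools. The deposited value table gives a background-subtracted intensity per probe and array on a linear scale. The method of background subtraction and normalization is not stated. Of these values 25.7% lay below 0, the highest was 28571 intensity units, the column medians ran from 14.6 to 14.7, and the columns differed by at most 0.190 intensity units at any rank, so the arrays had been put on 1 shared distribution. A further table with 32 columns of per-sample values names arrays by chip position, which matches no sample's labels, and was not used. Detection p values and control probes were therefore not used either, and the planned correction with them was replaced, after the tables had been examined, by the steps below.

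The deposited intensities were corrected with the normexp model in limma 3.58.1 (R 4.3.3) with an offset of 16 and put on the log2 scale, with no further normalization between arrays. The offset shrinks fold changes of dim probes. A background SD was estimated for each array from its negative values mirrored around 0, and the detection floor was 1.645 times that SD, or 8.87 to 8.93 intensity units. A probe was tested when it exceeded the floor on at least 2 of the 8 arrays, which left 15944 probes (62.0%), 948 of them without a gene name. Where all arrays of a group lay below the floor, the change is given as a lower limit against the floor. Of all probes 23978 carried 1 gene symbol and 1719 carried none, and 23962 were matched through the reference gene table. The genome build behind the probes is not named, so no coordinates are given.

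A linear model with the 3 groups was fitted to all 8 arrays with lmFit and eBayes of limma, without other terms, which left 5 residual and 5.64 prior degrees of freedom. The comparisons were AdCre against AdLacZ, AdLacZ against untreated and AdCre against untreated. A probe passed at a Benjamini-Hochberg adjusted p under 0.05 over all tested probes, and errors of log2 changes are limma's moderated standard errors. All tests were 2-sided. Changes are given on the log2 scale.

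Before the data were examined, 31 gene lists with 676 members were fixed for pathways, limb tissue, stress, virus response and other cell types that a limb bud culture could hold. Of the members 604 had a named probe and 495 were tested, with the probe of the highest mean for each gene. The 29 lists with at least 5 measured members were tested with camera in limma at a preset correlation of 0.01, with the adjusted p taken over these lists. The test was repeated with an estimated correlation, where camera also works with the 5 residual degrees of freedom, and with fry. Members past the threshold were counted with adjustment over all probes and over each list alone.

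Named genes followed a rule fixed at the same time. It takes Sox4, Sox11, Sox12, Tead2 and any other Sox gene past the threshold. Tead2 was put in the rule because it was already known as a gene that the study followed up, so it was not a blind choice. The rule adds the 14 largest rises and 14 largest falls in AdCre against AdLacZ and the 8 and 8 in each other comparison, among probes that passed with no overlap between groups. It also takes up to 4 members of each list by smallest p. No probe was named Sox11, which was not analysed here.

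Probes shared between comparisons with common arrays were set beside the number expected for independent lists and beside 100 simulated data sets without any effect. Detection was tested on simulated data with 200 changed probes in 10 runs, in which 5.59% of the called probes were unchanged ones. Alternatives covered background correction, normalization, filtering, array weights, the prior variance, the replicate number as a block, probe averaging, an ordinary test per probe and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.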

Results

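Gene expression was measured with Illumina bead arrays in primary cells from the forelimb and hindlimb buds of mouse embryos at embryonic day 11.5. The embryos carried floxed alleles of Sox4 and Sox11, in which sites for Cre recombinase flank part of the gene. Sox4, Sox11 and Sox12 make up the SoxC group of transcription factors. The title of the series concerns their part in the survival of neural and mesenchymal progenitors. The cells were cultured for 6 h and then left untreated (n = 2 arrays) or treated for 24 h with an adenovirus that expressed LacZ (AdLacZ, n = 3) or Cre recombinase (AdCre, n = 3). Each array held 25697 probes, of which 14358 to 14385 (55.9% to 56.0%) lay above the detection floor. In all, 15944 probes were tested, covering 10772 named genes. The number of arrays limits the precision: the median standard error of a log2 change was 0.119 for AdCre against AdLacZ and 0.134 against untreated cells. Nothing states that the replicates were separate cultures or came from separate litters, so the p values measure the spread between these arrays.

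AdCre cells were compared with AdLacZ cells to show the effect of Cre in cells with floxed SoxC genes while both arms carried virus. No arm gave AdCre to cells without floxed alleles, so effects of Cre itself cannot be told apart from those of the deletion. Sox4 fell by 1.31 ± 0.13 on the log2 scale (SE, a 2.48-fold decrease, adjusted p = 0.00114), from 6.69 ± 0.09 (SD, n = 3) in AdLacZ cells to 5.38 ± 0.03 (SD, n = 3) in AdCre cells. The size of this fall depended on the background correction, with -2.63 without it and -0.86 with an offset of 50, and Sox4 passed in both. Tead2, which encodes a DNA-binding partner of the co-activators YAP and TAZ, fell by 1.47 ± 0.11 (2.76-fold, adjusted p = 1.91e-04). Mt1, which encodes the metal-binding protein metallothionein 1, showed the largest rise, at 16.5-fold (log2 4.05 ± 0.15, adjusted p = 6.89e-07). Genes of DNA replication were lower as a group (adjusted p = 4.02e-08, but adjusted p = 0.07 with an estimated correlation). So were erythroid genes (adjusted p = 0.001, but adjusted p = 0.391 with an estimated correlation). Genes for apoptosis regulators and caspases did not pass as a group (adjusted p = 0.713). Sox12, whose gene was not floxed, differed by -0.24 ± 0.11 (adjusted p = 0.226), and Sox11 was not analysed here. Adjusted over the list alone, both measured SoxC genes, Sox4 and Sox12, passed as lower. With only 2 measured genes, however, Sox12 passed there at its unadjusted limma p of 0.0485. The Sox4 probe (ILMN_2893417) read 10.9 to 12.9 intensity units in AdCre cells, close to the highest detection floor of 8.93. Its position relative to the deleted part of the gene is not known here.

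**Figure D1:**
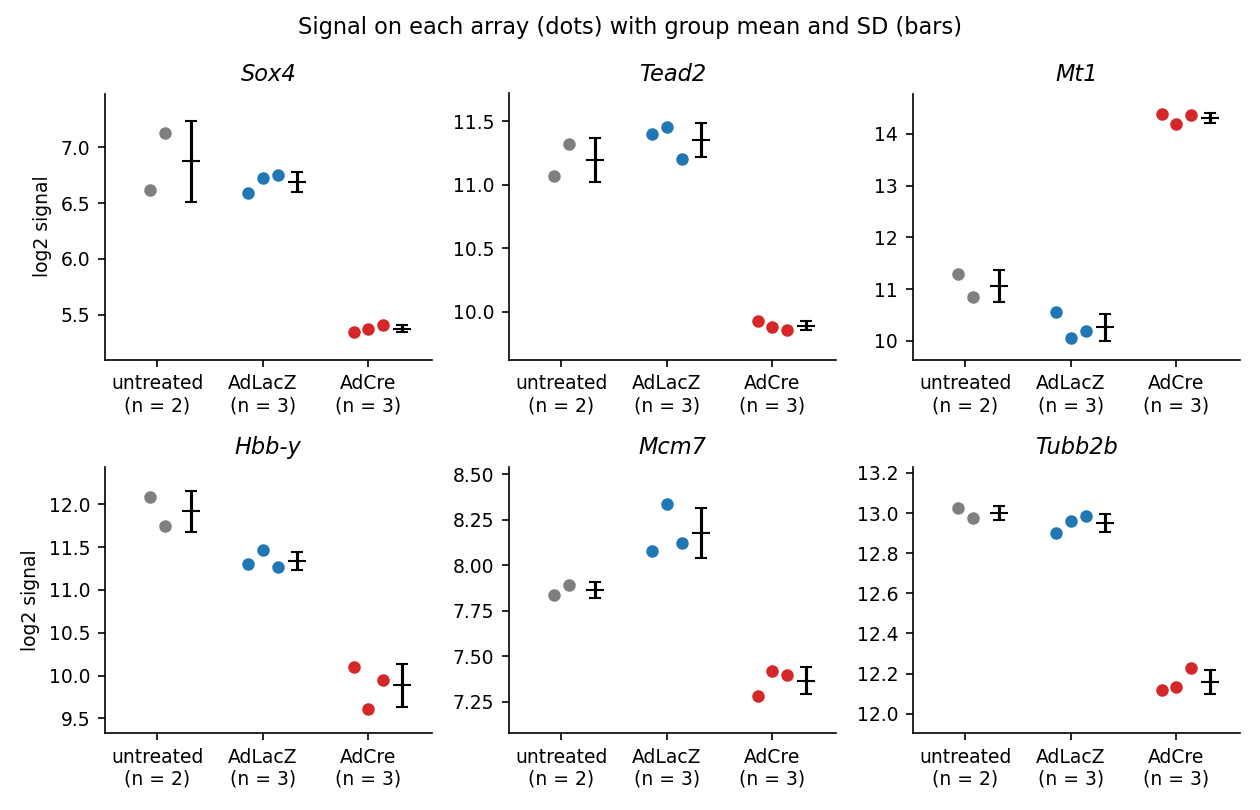
Log2 signal of 6 genes on each of the 8 arrays (dots) in untreated cells (grey, n = 2), AdLacZ cells (blue, n = 3) and AdCre cells (red, n = 3), with ticks for the group mean and bars for 1 SD. Mt1 lay at 14.3 in AdCre cells against 10.3 in AdLacZ cells, and the AdCre arrays lay below all others for Sox4 (5.34 to 5.41), Tead2, Hbb-y, Mcm7 and Tubb2b, the last chosen after its values were seen.

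In AdCre against AdLacZ cells, 802 probes passed the threshold, of which 253 were higher (196 genes) and 549 were lower (300 genes). The median size of their change was 0.55. Only 30 of them changed by more than 2-fold, 5 upward (Mt1, Dctn1, Psmg2, Slc16a6 and Cd248, the last chosen after its values were seen and 0.23 on its brighter probe) and 25 downward. The largest falls were those of Rapgef6, an activator of Rap GTPases (-2.02 ± 0.15), Zcchc18 (-1.51 ± 0.10) and Tead2. Rapgef6 was above the floor on only 1 of 3 AdCre arrays, so the size of its fall is measured against values near background. Next came the globin gene Hbb-y (-1.46 ± 0.14), Igsf9, a neuronal adhesion molecule (-1.46 ± 0.17), the kinase gene Sbk1 (-1.45 ± 0.13) and Efna4, an ephrin ligand (-1.43 ± 0.17). The globin gene Hba-a1 (-1.39 ± 0.14) and Sox4 followed. Zfp184 (-1.31 ± 0.15), the RNA-binding protein gene Mex3a (-1.29 ± 0.11), Ctxn1 (-1.07 ± 0.10) and the monoamine transporter gene Slc29a4 (-1.05 ± 0.11) fell as well. Zfp184 too was above the floor on only 1 of 3 AdCre arrays. Hnrnpa2b1, which encodes a splicing factor, fell by 1.06 ± 0.18 on its brightest probe. Another of its probes gave 0.51, and the mean over its probes was -0.27 (adjusted p = 0.297). After Mt1, the rises were smaller. They were led by Dctn1, a dynactin subunit (1.53 ± 0.33), the proteasome assembly factor gene Psmg2 (1.10 ± 0.14, but 0.08 on another probe), Pigt, part of the GPI transamidase (1.0 ± 0.11), and the antioxidant enzyme gene Gpx3 (0.90 ± 0.16). Gmppb (0.87), the synaptic scaffold gene Dlg4 (0.84), Slc16a6 (0.82, with 3 probes between -0.24 and 1.05), Ydjc (0.81), Tmem69 (0.80), Etfb (0.78) and Ccnk (0.78) rose by similar amounts. Tmem69 and Ccnk were above the floor on only 1 of 3 AdLacZ arrays. The matrix proteoglycan gene Prelp and Cdc26 were not above the floor in AdLacZ cells and rose at least 1.55-fold and 1.48-fold. The adjusted p values of these named genes ran up to 0.0285. All but 2 passed with each of the 8 arrays left out in turn. Dctn1 ended without AdLacZ replicate 3 or any 1 of the AdCre arrays (adjusted p up to 0.0816), and Cdc26 without those and without AdLacZ replicate 2 (up to 0.0999). The AdLacZ values of Dctn1 had an SD of 0.90. Without background correction Dctn1, Prelp, Gpx3, Ccnk, Cdc26, Zfp184 and Hnrnpa2b1 did not pass (adjusted p = 0.169, 0.0626, 0.0755, 0.118, 0.119, 0.0579 and 0.0723). Their changes were not smaller there, at 2.08, 3.52, 1.06, 3.03, 3.33, -2.99 and -1.07. In an ordinary test per probe Psmg2, Gmppb, Dlg4, Igsf9 and Efna4 did not pass (adjusted p = 0.0522, 0.0544, 0.05, 0.0511 and 0.0544). Nor did Dctn1, Gpx3, Ccnk, Cdc26 and Hnrnpa2b1 in that test (adjusted p = 0.17, 0.0946, 0.0724, 0.141 and 0.101), and Dctn1 did not pass with trend and robust fitting (adjusted p = 0.107).

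Of the 24 measured genes of DNA replication and S phase, 6 fell and 0 rose (10 fell and 0 rose adjusted over the list alone). Of the 24 changes 23 were negative, with a median of -0.23. The strongest falls were in Mcm7 (-0.81 ± 0.10) and Mcm3 (-0.73 ± 0.09), subunits of the replicative helicase, in the cyclin gene Ccne2 (-0.68 ± 0.11) and in Chaf1b (-0.57 ± 0.12), a histone chaperone subunit. The list was lower than other genes (camera adjusted p = 4.02e-08), which was lost with an estimated correlation (adjusted p = 0.07 with an estimated correlation). Among 19 mitosis and G2/M genes, 1 fell (Kif23, -0.41 ± 0.10, 1 fell adjusted over the list alone), and the list did not pass (adjusted p = 0.177). Among 24 p53 target genes, Dcxr rose (0.44 ± 0.10) and Trp53inp1 fell (-0.57 ± 0.12). There were 1 rise and 3 falls adjusted over the list alone (list adjusted p = 0.543). Among 22 apoptosis regulators and caspases, the protease genes Casp6 (-1.0 ± 0.12) and Casp2 (-0.48 ± 0.10) fell. There were 1 rise and 2 falls adjusted over the list alone (list adjusted p = 0.713). Among 20 genes of the TEAD and YAP pathway, Tead2 and the cofactor gene Vgll4 (-0.55 ± 0.10) fell, also 2 adjusted over the list alone. That list had a median of -0.05 and did not pass with camera (adjusted p = 0.223), but passed with fry (adjusted p = 0.0279). The calls of Chaf1b, Kif23, Dcxr, Trp53inp1, Casp2 and Vgll4 passed in 3, 2, 3, 4, 3 and 4 of the 8 fits that left out 1 array. Each virus-treated array ended at least 3 of these 6 calls when left out, with adjusted p values up to 0.133 (Kif23, without AdLacZ replicate 2).

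Of 8 measured erythroid genes 3 fell and 0 rose in AdCre against AdLacZ cells (5 fell and 1 rose adjusted over the list alone). The median was -0.39 and the list passed (adjusted p = 0.001, but adjusted p = 0.391 with an estimated correlation). The 3 were the globin genes Hbb-y (-1.46 ± 0.14), Hba-a1 (-1.39 ± 0.14) and Hba-x (-1.05 ± 0.16). Of 14 neuronal genes 2 fell (2 adjusted over the list alone), Stmn2 (-0.81 ± 0.15) and Dcx (-0.50 ± 0.11). The median of that list was -0.14 (adjusted p = 0.0312, but adjusted p = 0.391 with an estimated correlation). Of 36 limb mesenchyme patterning genes 3 fell (6 adjusted over the list alone), all of them transcription factor genes: Gli3 (-0.76 ± 0.15), Lhx9 (-0.53 ± 0.09) and Hand2 (-0.47 ± 0.12). The patterning list had a median of -0.08 (adjusted p = 0.0425, but adjusted p = 0.391 with an estimated correlation). Of 19 skeletal muscle genes 2 rose (3 adjusted over the list alone), Acta1 (0.55 ± 0.11) and Des (0.54 ± 0.10). Their median was 0.13 (adjusted p = 0.0312, but adjusted p = 0.528 with an estimated correlation). Of 18 contractile and smooth muscle genes 1 rose (1 adjusted over the list alone), Actg2 (0.61 ± 0.12). Their median was 0.16 (adjusted p = 0.0312, but adjusted p = 0.391 with an estimated correlation). Only the DNA replication and erythroid lists passed in all 18 other settings of the set test with the preset correlation. Without AdLacZ replicate 2 the neuronal, patterning, muscle and contractile lists were lost (adjusted p = 0.0954, 0.157, 0.101 and 0.107), and so they were without AdCre replicate 1 (adjusted p = 0.0611, 0.112, 0.125 and 0.112). The neuronal list was also lost without AdCre replicate 2 (adjusted p = 0.0502) and the patterning list without AdCre replicate 3 (adjusted p = 0.103). Without a filter on dim probes the neuronal, patterning and muscle lists did not pass (adjusted p = 0.0703, 0.0506 and 0.299). With array weights the patterning, muscle and contractile lists did not (adjusted p = 0.0844, 0.0602 and 0.0551), nor did the patterning list without background correction (adjusted p = 0.0563). The calls of Stmn2, Dcx, Gli3, Lhx9, Hand2, Acta1, Des and Actg2 passed in 4, 3, 4, 7, 2, 3, 5 and 4 of the 8 fits that left out 1 array. Each virus-treated array ended at least 4 of these 8 calls when left out, with adjusted p values up to 0.135 (Hand2, without AdLacZ replicate 3).

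The remaining 19 lists with a set test did not pass with camera in AdCre against AdLacZ cells. On the brightest probe of each gene, no member passed among 34 interferon and antiviral genes (median -0.10), 17 macrophage genes (median -0.03), 19 NF-kB and inflammatory genes or 7 other Sox genes. None passed among 5 neural crest and Schwann cell genes, 16 WNT targets, 15 BMP and TGF-beta targets, 8 Hedgehog targets, 9 Notch targets, 14 cholesterol synthesis genes and 7 replication-dependent histone genes. Adjusted over the list alone, these 11 lists gave 1 rise in cholesterol synthesis and 1 fall among Notch targets. A dimmer probe passed for the interferon-induced gene Gbp2 (-0.56), the Hedgehog receptor component gene Smo (-0.53) and the cholesterol synthesis gene Sqle (-0.57), all 3 chosen after their values were seen. In the fibroblast matrix list Col1a2, a collagen I gene (0.74 ± 0.10), and Timp3 (0.41 ± 0.10) rose and Fbln1 fell (-0.40 ± 0.10). Of the 25 genes 3 rose and 2 fell adjusted over the list alone. The matrix list passed with fry (adjusted p = 0.0309) but not with camera (adjusted p = 0.357). Single members rose among 11 cartilage genes (Matn4, 0.65 ± 0.16), 19 surface ectoderm genes (Krt19, 0.45 ± 0.11) and 11 heat shock genes (Hspb8, 0.46 ± 0.11), each also 1 rise adjusted over the list alone. Single members fell among 13 endothelial genes (Mmrn2, -0.67 ± 0.13), 20 hypoxia and glycolysis genes (Pgk1, not above the floor in AdCre cells and at least 1.30-fold lower) and 12 FGF feedback genes (Etv1, -0.79 ± 0.14). These lists had 1, 1 and 3 falls adjusted over the list alone. Among 23 genes of the unfolded protein and amino acid stress response Phgdh (-0.54 ± 0.11) and Pdia4 (-0.37 ± 0.09) fell. There were 2 rises and 4 falls adjusted over the list alone. Of the members named here, only Col1a2 and Pgk1 passed with each array left out. The adjusted p values of the others reached 0.0541 (Etv1) to 0.163 (Timp3), both without AdLacZ replicate 2. Each of the 8 arrays ended at least 4 of these calls when left out. Of 4 sex-linked genes 0 passed.

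**Figure D2:**
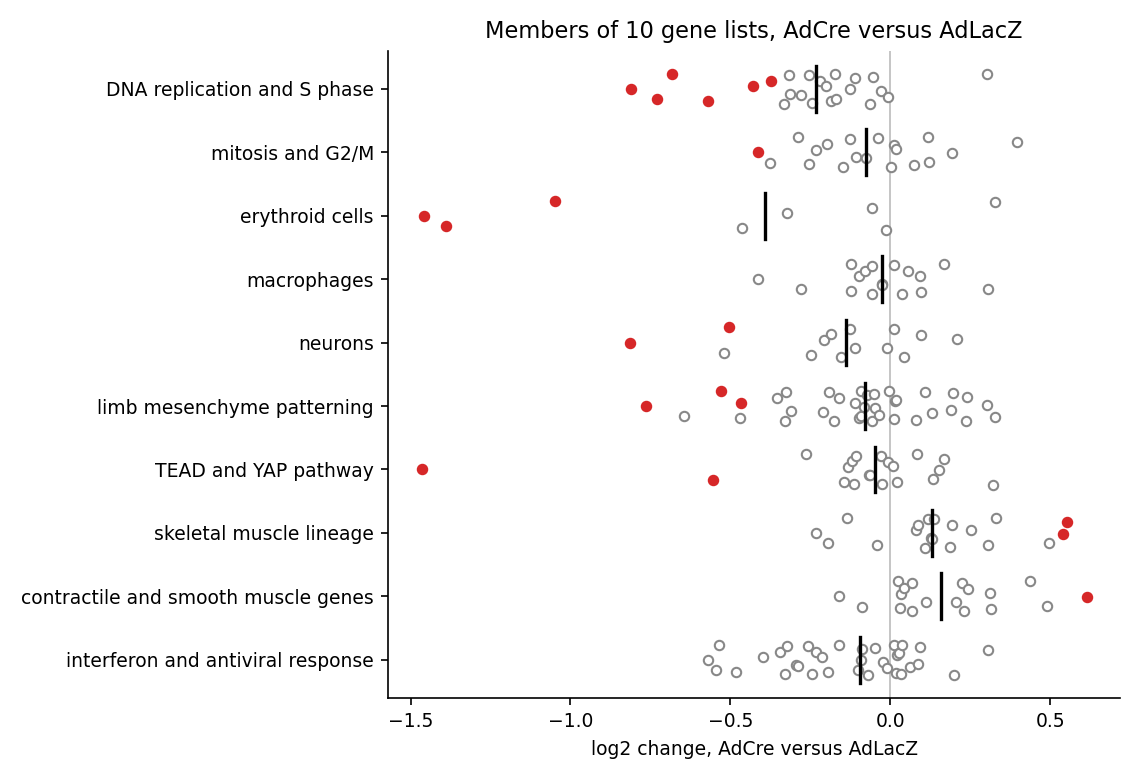
Log2 change in AdCre against AdLacZ cells (n = 3 and 3) for the members of 10 gene lists, 1 probe per gene, with adjusted p under 0.05 in filled red, other members as open circles and a black line at each list's median. The replication and erythroid lists lay to the left (medians -0.23 and -0.39), the muscle and contractile lists slightly to the right (0.13 and 0.16), and the macrophage list around 0 (-0.03).

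The test was limma with a Benjamini-Hochberg adjusted p under 0.05. In this comparison 3471 probes had an unadjusted p under 0.05. The values of the AdCre and AdLacZ arrays did not overlap for 28.4% of all tested probes, where chance gives 10%, and for all 802 that passed. Simulated data of the same design had 200 changed probes. There 51.0% of changes of 0.5, 99.8% of changes of 1 and 100% of changes of 1.5 on the log2 scale were called. Changes of 0.5 or less were thus often not detectable in such data. The adjusted threshold is looser when more probes change, and 802 passed here, so these shares may be too low for this comparison. The count depended on every virus-treated array. It was 433, 192 and 283 probes without AdLacZ replicates 1, 2 and 3, and 360, 294 and 353 without AdCre replicates 1, 2 and 3. Of the 58 genes past the threshold that were named by rule, 33 passed with each array left out in turn. Calls ended without AdLacZ replicates 1, 2 or 3 (15, 21 and 21 genes), AdCre replicates 1, 2 or 3 (18, 22 and 17) or either untreated array (4 and 4).

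AdLacZ cells were compared with untreated cells to show the effect of the virus. The labels give 24 h of treatment for the virus arms and no time for untreated cells, so a difference in time in culture is not separated from that of the virus. Interferon-induced genes rose most. Usp18, which encodes a protease that removes ISG15 from proteins, rose 11.5-fold (log2 3.52 ± 0.63, adjusted p = 0.0104). Isg15, the gene of that ubiquitin-like modifier, rose 8.80-fold (3.14 ± 0.40, adjusted p = 0.00199). The next were Ifit3 (2.79 ± 0.40), Rsad2 (2.71 ± 0.40), Gbp3 (2.71 ± 0.37), Oasl2 (2.54 ± 0.37), Igtp (2.53 ± 0.36) and Gbp2 (2.34 ± 0.29), all antiviral or interferon-induced genes. The errors given for these rises assume 1 spread for all 3 groups. Usp18, however, had an SD of 2.20 in untreated cells (n = 2) and 0.10 in AdLacZ cells (n = 3). The untreated SDs of the others ran from 0.84 (Gbp2) to 1.32 (Rsad2). The size of these rises depended on the untreated array. Usp18 rose by 1.97 without untreated replicate 1 and by 5.07 without untreated replicate 2, Isg15 by 2.25 and 4.02, and Ifit3 by 1.97 and 3.62. The other 5 rose by 1.71 to 1.83 without untreated replicate 1 and by 2.94 to 3.65 without untreated replicate 2. Igtp was above the floor on only 1 of 2 untreated arrays, so its rise without untreated replicate 2 is measured against a value at background. The largest falls were in the matrix metalloproteinase gene Mmp3 (-1.92 ± 0.14, 3.79-fold, adjusted p = 1.99e-04), the matrix proteoglycan gene Dcn (-1.79 ± 0.14) and the lysozyme gene Lyz1 (-1.77 ± 0.16). Angptl7 (-1.72 ± 0.13), the neuropeptide gene Adcyap1 (-1.63 ± 0.13), the lysozyme gene Lyz2 (-1.58 ± 0.21) and the prostaglandin-degrading enzyme gene Hpgd (-1.42 ± 0.15) followed. Both lysozyme genes are expressed in macrophages. Fcer1g, a signalling chain of immune receptors, was not above the floor in AdLacZ cells and fell at least 2.68-fold. Sox4 (-0.19 ± 0.15, adjusted p = 0.509), Tead2 (0.16 ± 0.12, adjusted p = 0.5) and Sox12 (0.32 ± 0.12, adjusted p = 0.157) did not pass. Sox4 was at 0.07 without untreated replicate 2. Adjusted over the list alone, Sox12 rose.

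Between AdLacZ and untreated cells 834 probes passed, 435 higher (317 genes) and 399 lower (278 genes). Of these 138 changed by more than 2-fold, 92 upward and 46 downward. In the interferon and antiviral list 26 of 34 measured members rose and 0 fell (30 rose and 0 fell adjusted over the list alone). Their median was 1.45 (camera adjusted p = 2.55e-28, but adjusted p = 0.212 with an estimated correlation). Irf7 (at least 1.93-fold), Oas1g (2.04 ± 0.21), Ddx58, a sensor of viral RNA (1.54 ± 0.16), and Parp14 (2.11 ± 0.25) had the smallest p values. Untreated replicate 2 lay between untreated replicate 1 and the AdLacZ arrays for these genes. The log2 signal of Usp18 was 8.95 there, 5.85 in untreated replicate 1 and 10.81 to 11.02 in AdLacZ cells. That of Isg15 was 7.90, 6.13 and 9.84 to 10.54. Among 17 macrophage genes 5 fell and 0 rose (11 fell and 1 rose adjusted over the list alone). They were Fcer1g, Lyz2, Cx3cr1 (-0.70 ± 0.11), C1qc (-0.81 ± 0.17) and Coro1a (-0.60 ± 0.14, chosen after its values were seen). The macrophage median was -0.44 (adjusted p = 8.31e-07, but adjusted p = 0.169 with an estimated correlation). Among 8 erythroid genes Car2 (-1.17 ± 0.14) and Hbb-bh1 (-0.89 ± 0.16) fell (6 fell adjusted over the list alone). The erythroid median was -0.56 (adjusted p = 0.00136, but adjusted p = 0.212 with an estimated correlation). Among 19 skeletal muscle genes the sarcomere gene Ttn (1.18 ± 0.18), Chrng (0.58 ± 0.11), Mylpf (0.55 ± 0.12) and Mymk (0.63 ± 0.15) rose (6 adjusted over the list alone). The muscle median was 0.27 (adjusted p = 1.48e-05, but adjusted p = 0.212 with an estimated correlation). Without untreated replicate 1 the calls of C1qc, Hbb-bh1, Chrng, Mylpf and Mymk ended (adjusted p = 0.0716, 0.0773, 0.143, 0.116 and 0.299). Those of C1qc and Mylpf ended without untreated replicate 2 (adjusted p = 0.108 for both). C1qc, Chrng, Mylpf and Mymk also ended without at least 1 AdLacZ array, and Mymk without each AdCre array (adjusted p up to 0.113).

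Of 7 other Sox genes 3 rose in AdLacZ against untreated cells (4 adjusted over the list alone), with a list adjusted p = 0.00639, but adjusted p = 0.212 with an estimated correlation. They were Sox9, a regulator of cartilage formation (0.64 ± 0.13, adjusted p = 0.0221), Sox5 (0.60 ± 0.13, adjusted p = 0.0219) and Sox7 (0.52 ± 0.13, adjusted p = 0.0391). The other probes of Sox5 and Sox7 gave 0.10 and 0.05. As means over their probes these genes did not pass (0.35, adjusted p = 0.0614, and 0.29, adjusted p = 0.132), nor did they with the replicate number as a block (adjusted p = 0.0518 and 0.0714). Sox7 also ended with an offset of 50, without a filter on dim probes, with array weights and with only the compared groups (adjusted p = 0.0521, 0.0832, 0.0608 and 0.0752). Among 11 cartilage genes the collagen gene Col2a1 rose (1.26 ± 0.13, 3 rises adjusted over the list alone). That list had adjusted p = 0.0088, but adjusted p = 0.212 with an estimated correlation. Among 9 Notch targets Notch1 (0.65 ± 0.12) and Notch3 (0.64 ± 0.13) rose (3 adjusted over the list alone). The Notch list had adjusted p = 0.044, but adjusted p = 0.266 with an estimated correlation. The replication list was higher (median 0.17, adjusted p = 0.0153, but adjusted p = 0.212 with an estimated correlation). Its only member past the threshold, Rrm2, fell (-0.44 ± 0.10), and 1 rose and 1 fell adjusted over the list alone. Cholesterol synthesis was lower (list adjusted p = 0.00136, but adjusted p = 0.212 with an estimated correlation), with 1 of 14 genes fallen (Mvd, -0.56 ± 0.10) and 5 adjusted over the list alone. FGF feedback genes were lower (list adjusted p = 0.00383, but adjusted p = 0.212 with an estimated correlation), with 1 of 12 fallen (Spred2, -0.56 ± 0.14) and 5 adjusted over the list alone. Replication-dependent histones were lower (list adjusted p = 0.0153, but adjusted p = 0.212 with an estimated correlation), with 1 of 7 fallen (H4c3, -0.63 ± 0.12) and 2 adjusted over the list alone. Of 36 patterning genes, which did not pass as a list, 3 rose and 3 fell (3 and 3 adjusted over the list alone). The proximal limb genes Meis1 (1.25 ± 0.16) and Meis2 (1.08 ± 0.13) were up and Tfap2a (-1.10 ± 0.12) was down. Without untreated replicate 1 the calls of Sox9, Sox5, Sox7, Notch1, Notch3, Rrm2, Mvd, Spred2 and H4c3 ended (adjusted p = 0.197, 0.158, 0.275, 0.111, 0.177, 0.264, 0.103, 0.0793 and 0.077). Of these genes Sox5, Sox7, Spred2 and H4c3 also ended without untreated replicate 2 (adjusted p = 0.0599 to 0.214), and Sox9, Sox5, Sox7, Notch3, Rrm2, Spred2 and H4c3 without at least 1 AdLacZ array (adjusted p up to 0.14). Sox7, Rrm2 and Spred2 ended without at least 1 AdCre array as well, and Spred2 passed in 0 of the 8 fits that left out 1 array. The other Sox, cartilage and Notch lists were lost without untreated replicate 1 (adjusted p = 0.0631, 0.129 and 0.172), and the replication and histone lists without untreated replicate 2 (adjusted p = 0.0627 and 0.123). The Notch list passed in 10 of 18 other settings, and was also lost without AdLacZ replicate 3 (adjusted p = 0.143) and without AdCre replicate 3 (adjusted p = 0.0567). Without a filter on dim probes the other Sox, cartilage and Notch lists did not pass (adjusted p = 0.269, 0.0577 and 0.187), nor did the replication and histone lists with the replicate number as a block (adjusted p = 0.0523 and 0.0517).

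The 17 other lists with a set test did not pass with camera in AdLacZ against untreated cells. Among them the WNT list passed with fry (adjusted p = 0.039). Of 25 fibroblast matrix genes 2 rose and 4 fell (3 and 5 adjusted over the list alone). The fallen genes included Dcn and Lum, the last of which was not above the floor in AdLacZ cells and at least 1.68-fold lower. Of 19 NF-kB and inflammatory genes Icam1 rose (0.78 ± 0.11) and Ccl7 (-1.18 ± 0.15) and Cxcl1 (-0.60 ± 0.12) fell. Of 15 BMP and TGF-beta targets 2 rose, with Tgfbi at 0.75 ± 0.12, and 3 fell, with the BMP antagonist gene Nog at -0.84 ± 0.15. Of 13 endothelial genes Robo4 rose (0.52 ± 0.11) and Tek fell (-0.69 ± 0.17). Of 20 hypoxia and glycolysis genes Hk2 rose (0.45 ± 0.11) and Slc2a1 fell (-0.56 ± 0.11). Adjusted over the list alone, these 4 gave 1, 2, 2 and 3 rises and 2, 3, 1 and 1 falls. Of 16 WNT targets 3 rose, with Apcdd1 at 0.88 ± 0.12 (4 adjusted over the list alone). Of 14 neuronal genes Dcx (0.56 ± 0.13) and Isl1 (0.46 ± 0.10) rose, with 3 rises and 2 falls adjusted over the list alone. Of 19 surface ectoderm genes the keratin gene Krt14 rose (1.0 ± 0.14), with 3 rises and 1 fall adjusted over the list alone. Of 19 mitosis genes Ccnf rose (0.62 ± 0.13), with 2 rises and 1 fall adjusted over the list alone. Of 22 apoptosis genes Casp1 rose, from below the floor in untreated cells and by at least 1.05-fold (0 adjusted over the list alone). Of 24 p53 targets Ei24 fell (-0.52 ± 0.11, also 1 adjusted over the list alone). On the brightest probe of each gene, no member passed among 20 TEAD and YAP pathway genes, 18 contractile genes, 5 neural crest genes, 8 Hedgehog targets, 23 unfolded protein response genes and 11 heat shock genes. These gave 3, 0, 1, 0, 2 and 0 rises and 0, 0, 1, 0, 2 and 0 falls adjusted over the list alone. A dimmer probe of Ankrd1, of the TEAD and YAP list, passed (0.68, chosen after its values were seen). Of 4 sex-linked genes Xist rose (0.53 ± 0.10), and with adjustment over the list alone 1 rose and 2 fell. Without untreated replicate 1 the calls of Icam1, Cxcl1, Tgfbi, Nog, Robo4, Tek, Hk2, Slc2a1, Dcx, Isl1, Krt14, Ccnf, Casp1, Ei24 and Xist ended (adjusted p = 0.052 to 0.277). Without untreated replicate 2 those of Nog, Robo4, Tek, Hk2, Slc2a1, Dcx, Isl1, Ccnf, Casp1, Ei24 and Xist ended (adjusted p = 0.0527 to 0.129). Cxcl1, Robo4, Tek, Hk2, Slc2a1, Dcx, Isl1, Ccnf, Casp1, Ei24 and Xist ended without at least 1 AdLacZ array (adjusted p up to 0.134), and Tek, Hk2 and Casp1 without at least 1 AdCre array (up to 0.0752). Casp1 passed in 0 of the 8 fits that left out 1 array.

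In this comparison 3316 probes had an unadjusted p under 0.05, and 38.4% of all tested probes did not overlap between the AdLacZ and untreated arrays, where chance gives 20%. The count was 168 without untreated replicate 1, 669 without untreated replicate 2 and 442, 459 and 390 without AdLacZ replicates 1, 2 and 3. Of 66 genes past the threshold that were named by rule 30 passed with each array left out. Calls ended without untreated replicates 1 or 2 (36 and 20 genes), AdLacZ replicates 1, 2 or 3 (19, 22 and 21) or AdCre replicates 1, 2 or 3 (6, 6 and 4). Without background correction the 8 interferon-induced genes with the largest rises did not pass, although they rose by 2.76 to 4.57 (adjusted p = 0.0575 to 0.137), nor did Lyz2 (0.104), Sox5, Sox7 and Sox9. The same 12 genes did not pass in an ordinary test per probe (adjusted p = 0.0664 to 0.13), nor did Usp18 with trend and robust fitting (adjusted p = 0.0792).

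AdCre cells were also compared with untreated cells, a comparison that holds the effects of virus, Cre and any difference in time in culture together. Mt1 rose 9.48-fold (log2 3.25 ± 0.17, adjusted p = 2.22e-05). Sox4 fell by 1.5 ± 0.15 (2.83-fold, adjusted p = 3.56e-04) and Tead2 fell by 1.31 ± 0.12 (2.47-fold, adjusted p = 2.81e-04). The other large rises were in interferon-induced genes: Usp18 (3.23 ± 0.63), Isg15 (2.6 ± 0.40), Ifit3 (2.58 ± 0.40), Rsad2 (2.55 ± 0.40), Igtp (2.50 ± 0.36), Samd9l (2.37 ± 0.20) and Oasl2 (2.29 ± 0.37). Here too the errors assume 1 spread for all 3 groups. Without untreated replicates 1 and 2 in turn Usp18 rose by 1.68 and 4.78, Isg15 by 1.72 and 3.48 and Ifit3 by 1.76 and 3.40. Rsad2 rose by 1.62 and 3.49, Igtp by 1.69 and 3.32, Samd9l by 1.99 and 2.75 and Oasl2 by 1.48 and 3.11. Igtp was above the floor on only 1 of 2 untreated arrays, so its 3.32 is measured against a value at background. Usp18, Rsad2 and Igtp did not pass without background correction, although they rose by 3.77, 3.23 and 4.55 (adjusted p = 0.0801, 0.0541 and 0.0845). In an ordinary test per probe Usp18, Isg15, Ifit3, Rsad2, Igtp and Oasl2 did not pass (adjusted p = 0.0517 to 0.102), nor did Usp18 with trend and robust fitting (adjusted p = 0.0656). The largest falls were in Rapgef6 (-2.15 ± 0.16), the globin gene Hbb-y (-2.03 ± 0.16), Lyz2 (-1.99 ± 0.21), Lyz1 (-1.95 ± 0.16) and the globin gene Hba-a1 (-1.94 ± 0.15). Rapgef6 was above the floor on only 1 of 3 AdCre arrays. Adcyap1 (-1.87 ± 0.13) and Angptl7 (-1.75 ± 0.13) fell too, and Fcer1g was not above the floor in AdCre cells and at least 2.68-fold lower. Sox9 (0.63 ± 0.13), Sox5 (0.45 ± 0.13) and Sox7 (0.45 ± 0.13) rose, but these calls ended without untreated replicate 1 (adjusted p = 0.108, 0.174 and 0.241). Sox5 and Sox7 also ended without untreated replicate 2, AdLacZ replicate 3 or any 1 of the AdCre arrays (adjusted p up to 0.105). The other probes of Sox5 and Sox7 gave 0.01 and 0.13, and as means over their probes these genes did not pass (0.23, adjusted p = 0.147, and 0.29, adjusted p = 0.0903). Nor did they without a filter on dim probes, with array weights or with the replicate number as a block (adjusted p = 0.0536 to 0.0845). Sox7 also ended with an offset of 50, with trend and robust fitting and with only the compared groups (adjusted p = 0.0724, 0.0628 and 0.052), and Sox5 without background correction (adjusted p = 0.0576). In an ordinary test per probe Sox9, Sox5 and Sox7 did not pass (adjusted p = 0.0587, 0.089 and 0.0944). Adjusted over the list alone, Sox4 fell and Sox12 did not pass. Sox12 was at 0.08 ± 0.12 (adjusted p = 0.713), or -0.01 as the mean over its probes.

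Between AdCre and untreated cells 2183 probes passed, 1054 higher (797 genes) and 1129 lower (653 genes), with 88 higher and 121 lower by more than 2-fold. In the interferon and antiviral list 26 of 34 genes rose and 0 fell (30 and 0 adjusted over the list alone). Their median was 1.29 (adjusted p = 7.69e-19, but adjusted p = 0.248 with an estimated correlation). In the skeletal muscle list 11 of 19 rose (13 adjusted over the list alone), among them Ttn (1.26 ± 0.18), Des (0.78 ± 0.11), the acetylcholine receptor gene Chrng (0.72 ± 0.11) and Acta1 (0.76 ± 0.13). The muscle median was 0.54 (adjusted p = 1.11e-07, but adjusted p = 0.231 with an estimated correlation). In the erythroid list 6 of 8 fell (6 adjusted over the list alone). The erythroid median was -1.10 (adjusted p = 8.41e-07, but adjusted p = 0.213 with an estimated correlation). In the macrophage list 8 of 17 fell and 1, the platelet factor gene Pf4 (0.81 ± 0.15), rose (11 and 1 adjusted over the list alone). The macrophage median was -0.42 (adjusted p = 8.41e-07, but adjusted p = 0.101 with an estimated correlation). Of 12 FGF feedback genes 6 fell (8 adjusted over the list alone). Among them were the transcription factor genes Etv1 (-1.02 ± 0.15) and Etv4 (-0.53 ± 0.10) and the phosphatase genes Dusp4 (-0.64 ± 0.12) and Dusp6 (-0.51 ± 0.11). The median of the FGF list was -0.44 (adjusted p = 1.19e-04, but adjusted p = 0.101 with an estimated correlation). Of 18 contractile genes Srf (0.59 ± 0.11), Lmod1, Tpm2 and Cnn1 rose (6 adjusted over the list alone). The contractile list had adjusted p = 0.02, but adjusted p = 0.231 with an estimated correlation. Of 24 replication genes Rrm2 (-0.77 ± 0.10), Mcm7 (-0.50 ± 0.12), Mcm3 (-0.47 ± 0.10) and Rrm1 fell and Ccne1 rose. The replication list was lower (4 falls and 1 rise adjusted over the list alone, list adjusted p = 0.0266, but adjusted p = 0.231 with an estimated correlation). Of 7 replication-dependent histones H3c7 (-0.65 ± 0.14) and H4c3 (-0.43 ± 0.12) fell (3 adjusted over the list alone). The histone list had adjusted p = 0.00819, but adjusted p = 0.231 with an estimated correlation. Of 14 cholesterol synthesis genes Sqle (-0.50 ± 0.12) and Lss (-0.44 ± 0.12) fell (6 adjusted over the list alone). The cholesterol list had adjusted p = 0.0461, but adjusted p = 0.324 with an estimated correlation. Without untreated replicate 1 the calls of Etv4, Dusp4, Dusp6, Srf, Tpm2, Cnn1 and Mcm7 ended (adjusted p = 0.0519, 0.0547, 0.128, 0.0554, 0.101, 0.0638 and 0.0809). Those of Mcm3, Ccne1, H3c7, H4c3, Sqle and Lss ended too (adjusted p = 0.0833, 0.213, 0.0803, 0.106, 0.182 and 0.159), and so did that of the cholesterol list (adjusted p = 0.258). Without untreated replicate 2 the calls of Lmod1, Tpm2, Cnn1, Mcm7, Mcm3, Ccne1, H4c3 and Lss ended (adjusted p = 0.0538 to 0.228). Tpm2, Cnn1, Mcm7, Ccne1, H4c3, Sqle and Lss ended without at least 1 AdCre array (adjusted p up to 0.118), and Cnn1 and Lss without at least 1 AdLacZ array (up to 0.0626). The replication and histone lists were lost without untreated replicate 2 (adjusted p = 0.0634 and 0.0615). Without AdCre replicate 1 the replication and cholesterol lists were lost (adjusted p = 0.064 and 0.095), and the cholesterol list also without AdLacZ replicate 2 (adjusted p = 0.0512). A stricter filter on dim probes, only the compared groups and the replicate number as a block also ended the cholesterol list (camera adjusted p = 0.0563, 0.0541 and 0.0555).

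**Figure D3:**
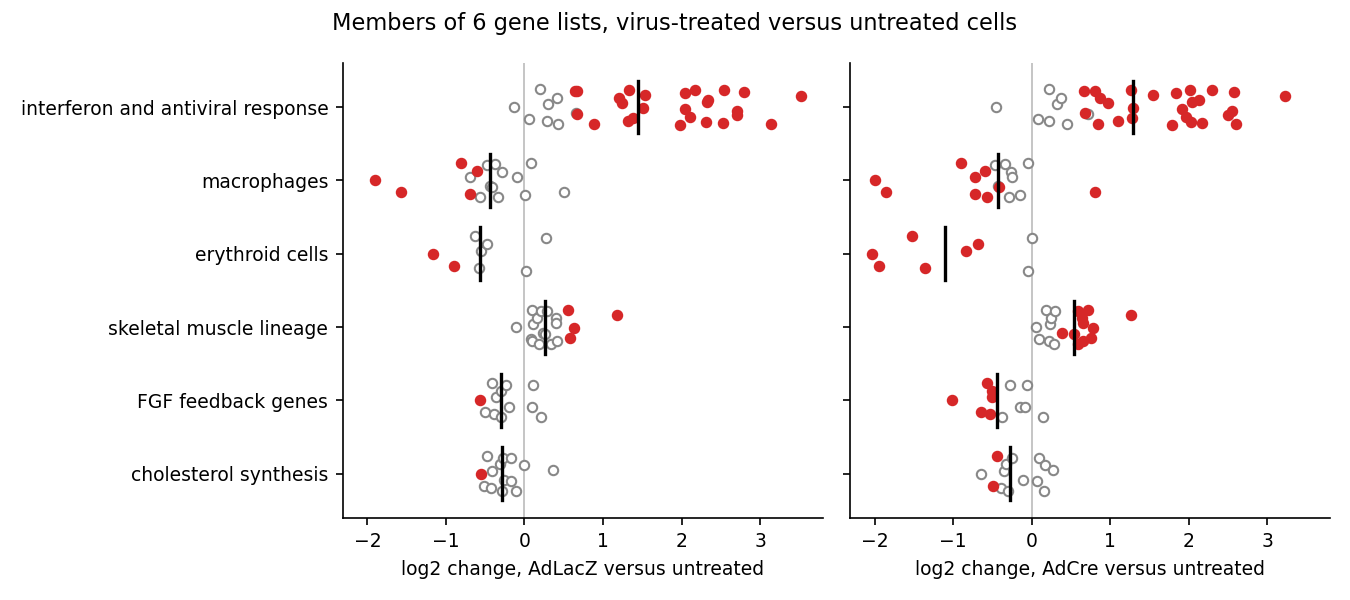
Log2 change against untreated cells (n = 2) in AdLacZ cells (left, n = 3) and AdCre cells (right, n = 3) for the members of 6 gene lists, 1 probe per gene, with adjusted p under 0.05 in filled red, other members as open circles and a black line at each list's median. Interferon genes lay to the right in both (medians 1.45 and 1.29), macrophage genes to the left (-0.44 and -0.42), and the erythroid median was -0.56 in AdLacZ cells and -1.10 in AdCre cells.

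The other 20 lists did not pass with camera in AdCre against untreated cells. With fry the surface ectoderm list (adjusted p = 0.00829) and the other Sox list (0.0216) passed. So did the TEAD and YAP, neuronal and WNT lists (fry adjusted p = 0.0206 each). The unfolded protein response list (0.0288) and the cartilage list (0.0443) passed with fry as well. Of 36 patterning genes 4 rose and 6 fell (4 and 6 adjusted over the list alone). Meis1 (1.16 ± 0.16) and Meis2 (0.99 ± 0.13) were up, and Tfap2a (-1.41 ± 0.12) and the distal limb gene Hoxd13 (-1.04 ± 0.20) were down. Of 19 surface ectoderm genes 4 rose and 1 fell (5 and 1 adjusted over the list alone), with the keratin genes Krt14 (1.17 ± 0.14), Krt8 (1.01 ± 0.18) and Krt18 (0.68 ± 0.11) up. Of 11 cartilage genes Col2a1 (0.96 ± 0.13), Matn4 (0.80 ± 0.18) and Pth1r (0.60 ± 0.14) rose (3 adjusted over the list alone). Of 25 fibroblast matrix genes 4 rose and 4 fell (6 and 4 adjusted over the list alone), with Dcn at -1.68 ± 0.14. Of 16 WNT targets 4 rose and 1 fell, Myc at -0.62 ± 0.11 (6 and 2 adjusted over the list alone). Of 15 BMP and TGF-beta targets 3 rose and 2 fell (3 and 3 adjusted over the list alone), with Nog at -0.87 ± 0.15. Falls without rises were seen among mitosis genes (3 of 19, Cdca8, Plk1 and Kif23) and TEAD and YAP pathway genes (Tead2 and Ajuba of 20). The same held for p53 targets (Ei24 and Trp53inp1 of 24), apoptosis genes (Casp6, -0.82 ± 0.13, and Casp2, -0.46 ± 0.11, of 22) and neuronal genes (Stmn2, -1.06 ± 0.17, of 14). These 5 lists gave 3, 2, 2, 2 and 1 falls adjusted over the list alone. Rises without falls were seen among other Sox genes (3 of 7) and Notch targets (Notch1 and Notch3 of 9), with 3 and 2 adjusted over the list alone and 1 fall among Notch targets. Of 19 NF-kB genes Icam1 rose (1.04 ± 0.11) and Cxcl1 (-0.81 ± 0.12) and Ccl7 (-0.75 ± 0.15) fell. Of 13 endothelial genes Robo4 and Flt1 rose and Tek fell (-0.98 ± 0.17). Of 23 unfolded protein response genes Herpud1 and Xbp1 rose and Slc7a11, Phgdh and Atf4 fell. Of 11 heat shock genes Hspb8 rose and Bag3 fell, and of 20 hypoxia genes 4 rose and 2 fell. On the brightest probe of each gene, no member passed among 8 Hedgehog targets or 5 neural crest genes, but a dimmer probe of Smo did (-0.42, chosen after its values were seen). Adjusted over the list alone, these 7 lists gave 1, 2, 4, 1, 4, 0 and 0 rises and 2, 1, 6, 1, 3, 0 and 1 falls. Of 4 sex-linked genes Xist rose (0.53 ± 0.10) and the Y-linked gene Kdm5d fell (-0.89 ± 0.18), also 1 and 1 adjusted over the list alone. Without untreated replicate 1 the calls of Hoxd13, Krt8, Matn4, Pth1r, Plk1, Kif23, Ei24, Trp53inp1, Casp2, Notch1 and Notch3 ended (adjusted p = 0.0552 to 0.317). Those of Ccl7, Robo4, Flt1, Tek, Slc7a11, Phgdh, Atf4, Hspb8, Bag3 and Kdm5d ended too (adjusted p = 0.0508 to 0.138). Without untreated replicate 2 those of Kif23, Ajuba, Ei24, Trp53inp1, Casp2, Flt1, Phgdh and Bag3 ended (adjusted p = 0.0542 to 0.124). Pth1r, Kif23, Ei24, Trp53inp1, Casp2, Notch1, Notch3, Flt1, Phgdh, Atf4 and Bag3 ended without at least 1 AdCre array (adjusted p up to 0.1), and Notch3 and Bag3 without at least 1 AdLacZ array (up to 0.0633).

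For AdCre against untreated cells 4543 probes had an unadjusted p under 0.05, and 43.3% of all tested probes did not overlap, where chance gives 20%. The count was 712 without untreated replicate 1 and 1626 without untreated replicate 2. Of 101 genes past the threshold that were named by rule 52 passed with each array left out. Calls ended without untreated replicates 1 or 2 (47 and 21 genes), AdCre replicates 1, 2 or 3 (19, 19 and 12) or AdLacZ replicates 1, 2 or 3 (2, 3 and 5).

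AdCre cells differed from both controls in the same direction at 474 probes, 126 higher and 348 lower. They made up 59.1% of the 802 probes that differed from AdLacZ cells. Another 8 probes differed from both controls in opposite directions, among them probes of Cxadr (-0.72 against AdLacZ and 0.68 against untreated cells), Ifi202b (-0.64 and 0.67) and Gbp2 (-0.56 and 0.60), chosen after their values were seen. All 14 genes with the largest falls against AdLacZ cells were also lower than in untreated cells, including Sox4, Tead2, Rapgef6, Zcchc18 (-1.46), Efna4 (-1.58), Ctxn1 (-1.22) and Hnrnpa2b1 (-1.33). Of the 14 with the largest rises 9 were also higher than in untreated cells, among them Mt1, Slc16a6 (1.06), Gpx3 (0.82), Gmppb (0.80) and Prelp (0.72). The other 5 were not, with Dctn1 at 0.17, Psmg2 at 0.12, Pigt at -0.06, Ccnk at -0.09 and Cdc26 at 0.46 (adjusted p = 0.137). Psmg2 (-0.98), Pigt (-1.06) and Ccnk (-0.88) had fallen in AdLacZ against untreated cells. Independent lists of these sizes would share 16.7 higher and 38.9 lower probes, and 100 simulated sets without any effect shared 0 at most. Sets without effects leave few calls to share, so they do not measure what the common arrays add when effects exist. Both comparisons use the same AdCre arrays, so part of the excess may come from them. The changes correlated across probes at 0.539, against 0.447 in the simulated sets, with a covariance of 0.0436 against 0.00847. Probes are not independent replicates. The count was 246 and 323 without untreated replicates 1 and 2, 277, 139 and 214 without AdLacZ replicates 1, 2 and 3, and 238, 207 and 239 without AdCre replicates 1, 2 and 3.

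The virus-treated groups shared 627 probes that differed from untreated cells in the same direction, 346 higher and 281 lower, or 75.2% of the 834 in AdLacZ cells. Without untreated replicate 1 they shared 137 of 168, and without untreated replicate 2 they shared 531 of 669. The shared count was 359, 394 and 335 without AdLacZ replicates 1, 2 and 3, and 494, 468 and 571 without AdCre replicates 1, 2 and 3. Only 2 probes differed in opposite directions, Mt1 (-0.80 in AdLacZ and 3.25 in AdCre cells) and Gpc2, a cell surface proteoglycan gene (0.49 and -0.52), both chosen after their values were seen in this comparison. Independent lists would share 28.8 higher and 28.2 lower probes, and simulated sets without any effect shared 0.03 on average and 1 at most. Here too, such sets leave few calls to share and do not measure what the common arrays add. The same untreated arrays enter both comparisons, and part of the excess may come from them. The changes correlated across probes at 0.715, against 0.6 in the simulated sets, with a covariance of 0.0698 against 0.0127.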

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

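The alternatives were chosen before the data were examined, but their detection limits had to be redefined from the negative values once the tables had been seen. Sox4 in AdCre against AdLacZ cells passed under every alternative run, with log2 changes of -2.63 without background correction and -0.86 with an offset of 50, and of -1.36 to -1.28 with 1 array left out. The numbers of passing probes depended more on the settings. They are given in the order AdCre against AdLacZ, AdLacZ against untreated, AdCre against both controls, with the main counts of 802, 834 and 474, and the direction kept its balance toward lower probes in the first and last. An offset of 50 gave 1420, 1440 and 793, and eBayes with trend and robust fitting gave 1432, 1500 and 799. Without background correction, with intensities floored at 1, there were 243, 262 and 173, and 1327 against the 2183 of AdCre against untreated. Without a filter on dim probes there were 406, 486 and 246, where 25697 probes share the adjustment. The ordinary test per probe, which shares no variance between probes, gave 314, 252 and 216, and 1238 for AdCre against untreated. The mean over the probes of a gene gave 514 genes and 289 genes for the first and last, where 10772 genes and not 15944 probes were tested. With the replicate number as a block there were 498, 442 and 272, but the replicate numbers did not pair the arrays: 7 same-number pairs correlated at -0.142 to 0.023 after removal of the group means. Cyclic loess, a stricter filter (13140 probes), array weights and a fit to only the compared groups left each probe count within 1.5 times the main count, the last not run for AdCre against both controls. With 1 array left out the 3 counts ran from 192 to 774, from 168 to 849 and from 139 to 323, and AdCre against untreated from 712 to 2008, where a lone untreated array is assumed to vary like the other groups. Fewer arrays give fewer degrees of freedom, and for the other shifts the cause was not tested. For gene lists, 6 passed in AdCre against AdLacZ, against 3 without a filter, 3 with array weights and 2 to 8 with 1 array left out. With an estimated correlation 0, 0 and 0 lists passed in the 3 comparisons, and fry called 6, 12 and 16, the last against 9 in AdCre against untreated. In AdCre against AdLacZ the 6 of fry were not the 6 of camera. Fry called the TEAD and YAP list (adjusted p = 0.0279) and the fibroblast matrix list (0.0309), but not the patterning (0.0691) and muscle lists (0.0769). The neuronal list was lost at an estimated correlation of -0.0247, below the preset of 0.01, so the size of the correlation alone does not account for every loss. Among genes named by size, with the named Sox genes and Tead2, 714 of 792 values under other settings kept their direction and side of the threshold. Of the rest 77 no longer passed and 1 reversed. With 1 array left out the numbers were 538, 37 and 1 of 576. These counts include Sox genes and Tead2 in comparisons where they had not passed in the main fit. Among all named genes 361 of 2517 values no longer passed under other settings, and 384 of 1832 when 1 array was left out. The reversed values had not passed: Sox12 in AdCre against untreated at -0.014 as the mean over probes, and Sox4 in AdLacZ against untreated at 0.0699 without untreated replicate 2, and at -0.44 without untreated replicate 1. The median log2 change over all tested probes lay between -0.014 and 0.014 in the main fit, with cyclic loess and with both other background settings. All of these start from the deposited columns, which were already on 1 shared distribution. A median near 0 was therefore given in advance and does not test the normalization. Scaling to a common median was not run because the medians were already equal to within 0.190 intensity units, the deposited table served as the source and so gave no separate alternative, and Sox11 was not run. Of all probes 55.9% to 56.0% lay above the detection floor per array, so changes in dimmer genes were not detectable.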

Other observations

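All tests in this part were chosen after the results they concern had been seen, except the counts over other splits of the arrays. In AdCre against AdLacZ cells, 5 of 1028 genes with at least 3 tested probes fell on every probe: the tubulin gene Tubb2b (5 probes, -1.09 to -0.73), the actin regulator gene Marcksl1 (4 probes, -1.04 to -0.64), Tmpo (-0.70 to -0.64), which encodes a protein of the nuclear envelope, Eif4e3 (-0.65 to -0.59) and Cep97 (-0.51 to -0.47), with a highest adjusted p of 0.0406. Gpc2, a proteoglycan gene of neural tissue, fell by 1.0 ± 0.10 (adjusted p = 0.00114). Among 263 gene families grouped by symbol, the Mcm family alone passed in this comparison, with 3 of 8 members fallen and a median of -0.30 (adjusted p = 9.99e-04, and 0.918 with an estimated correlation).

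Against untreated cells, AdLacZ cells had higher Hoxb genes, which pattern the body axis: Hoxb2 (0.77 ± 0.16), Hoxb4 (0.89 ± 0.19) and Hoxb5 (0.66 ± 0.15) rose, 3 of 6 measured, with a family median of 0.63 (adjusted p = 0.0152, and 0.857 with an estimated correlation). Annexin genes were lower, with Anxa1 (-0.75 ± 0.12) and Anxa4 (-1.02 ± 0.16) fallen among 8 (family adjusted p = 0.044, and 0.857 with an estimated correlation). Cxadr, which encodes the receptor of adenovirus, rose on 1 probe by 1.41 ± 0.20 in AdLacZ cells and by 0.68 ± 0.20 in AdCre cells, while its other probes gave -0.18 and 0.09 in AdLacZ cells. Along the first principal component (38.2% of the variance) untreated replicates 1 and 2 lay at -32.0 and -20.4, AdLacZ arrays at -0.44 to 2.48 and AdCre arrays at 15.9 to 16.2.

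Mt1 rose 16.5-fold in AdCre cells with no rise of similar size in any other named gene, the next being Dctn1 at 1.53. A broad metal or oxidative stress response is argued against by 7 genes of that response, whose median change was 0.156 (0 of 7 passed, highest upper 95% limit 0.53). The changes ran from -0.105 to 0.239, the highest in Slc30a1. The set did not separate genes that respond to metal from those that respond to oxidative stress, so a response to metal alone stays open. A glucocorticoid response is argued against by 4 of its target genes, whose median was -0.208 (0 of 4 passed, highest upper limit 0.38). A candidate explanation that stays open is Mt1 sequence carried by the Cre vector, since some Cre cassettes end in a metallothionein segment that a probe could detect. The sequences of the vector and the probe were not used here, and a response specific to Mt1 after loss of SoxC factors was not tested.

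Untreated replicate 2 had interferon gene values between those of untreated replicate 1 and the AdLacZ arrays, at a median of 21.5% of the way on the intensity scale (22 genes, quartiles 19.0% to 23.7%). Interferon signalling alone, with no change in other genes, would leave the 31 genes that fell over 2-fold in AdLacZ cells near 0. They lay at 31.9% of the way (quartiles 18.6% to 41.3%), with 27 of 31 above 0. Every share starts from untreated replicate 1, however. A deviation of that array from the others could raise all sets, so this test cannot settle the point. AdCre-treated material is argued against by Mt1, whose value differed by -1.79 from the one that share would give. A share of AdLacZ-treated material in that array stays open. It predicts about the same share in every set of genes, and the 42 other risen genes lay at 21.2% (quartiles 13.5% to 28.0%). The median of the fallen genes, however, lay above the upper quartiles of both risen sets. Many of the 42 are themselves interferon-induced, among them Samd9l, Irgm2, Gbp2b, Gbp7, Ifi47, Ifitm3, Ifi202b and Eif2ak2. The close medians of the risen sets therefore say little about genes outside the interferon response. Virus that reached part of the cells and ordinary variation between the arrays stay open as well. Counts without this array stand beside each comparison with untreated cells.

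Globin genes fell in AdCre against AdLacZ cells, and the tests run here decided between none of the explanations. Fewer red blood cells stays open. The 4 globin probes above 50 intensity units on every array fell by similar amounts (-1.57 to -1.19, a gap of 0.382), and the same probes lay at -0.58 to -0.48 in AdLacZ against untreated cells. These probes are 3 genes picked by brightness, while the fixed erythroid list had a median of -0.39 over 8 genes, with 5 fallen and 1 risen adjusted over the list alone. Of the 8, 3 were too dim to show such a fall. Among the 5 others, compared by mean deposited intensity, Hbb-bh1 fell by 1.11 but Car2, a gene not confined to red blood cells, rose by 0.60, so the 5 lay up to 2.08 apart. Loss of blood cells of every kind stays open as well. The 9 of 17 macrophage genes bright enough to show such a fall had a median of -0.039 (quartiles -0.25 to 0.22), with Lyz2 lowest at -0.98. That list had already fallen in AdLacZ against untreated cells, however, and Fcer1g was above the floor on 0 of 3 AdLacZ arrays, so part of the macrophage signal was gone before this comparison. The 9 bright genes were each still above the floor on 3 of 3 AdLacZ arrays, and as a set they showed no fall of the size seen in the globin probes. Whether the cells carried over into culture differed between the groups by chance, or were lost after Cre, was not tested.

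For AdCre against AdLacZ the 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 802 probes against 0 at most in the other 9, and 6 gene lists against 4 at most; in each case 1 split of 10, the real one, gave as many.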
